A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

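The deposited table holds normalized densities, read here as signal, for 10891 features in 10 libraries, with 5 further columns that equal the means of each pair of replicates. The submitters' processing notes name Trim Galore, HISAT2 2.2.0, featureCounts 2.0.0 and DESeq2 among the tools the authors used to make the deposited signal, without a role for each, and the R64 genome. The values themselves show how they were scaled: each is a whole number of reads divided by feature length and by a factor per library, for 100% of values at a tolerance of 0.02, and the 73 of 92 ERCC RNAs above 0 in all libraries have the same median deviation in each. The factors therefore follow the ERCC spike-in RNAs, which is inferred from the values and is not stated by the labels. The labels also do not state at which step, or per cell or per amount of RNA, the ERCC RNAs were added. A change per spike-in RNA is thus not known to be a change per cell. Recovered totals run from 16.0 M to 33.5 M reads per library, summed over feature rows, so reads shared by overlapping rows are counted in each.

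Features were classed by identifier as 5897 protein-coding genes, 1664 XUTs, 1526 NUTs, 925 CUTs, 678 reading frames without a RefSeq protein, 76 snoRNAs, 28 mitochondrial features, 4 features of the 2-micron plasmid and 1 other. Gene positions came from the RefSeq annotation of R64, matched for 5919 identifiers. Positions of XUTs, CUTs and NUTs were not in the files, so pairs of antisense transcripts and a set of features without overlaps were not analysed here, nor were SUTs, which have no entries.

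Features with a mean density under the 10th percentile of those above 0 (0.0344) were left out, which kept 9666 of 10740. The log2 of density plus 0.00616, the 5th percentile, was fitted with limma over all 10 libraries (lmFit and eBayes with a trend, 5 residual and 4.84 prior degrees of freedom), with a coefficient per group. An SE thus rests on the spread pooled over all 5 groups, not on that of the 2 groups compared. Calls use the limma adjusted p (Benjamini-Hochberg) under 0.05, and "relative" values come from the same fit after each library was rescaled on its median protein-coding gene. Lists and classes were tested with camera at a preset correlation of 0.01, lists against the protein-coding genes plus any other member of the list, classes against all kept features, and again with an estimated correlation. Class medians carry ranges over pairs of replicates and bootstrap intervals of 2000 draws, and 100 draws simulated the shared WT libraries. DESeq2 and edgeR with TMM factors, planned in case reads could be recovered, were not run although reads were recovered, because the value of a read depends on feature length and count tests were kept for values with a common step. Limma with voom weights was run on the recovered reads instead. Software: Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

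The groups, comparisons, 34 lists, filter, pseudocount and naming rule were fixed before the data were examined. Named in each mutant comparison are XRN1, DBP2, MTR4 and the strain markers, then, among features called with both mutant libraries beyond both controls, the 8 protein-coding genes of at least median density (0.394) with the largest rise and the 8 with the largest fall, 4 XUTs, 3 CUTs and 3 NUTs with the largest rise, 2 noncoding RNAs with the largest fall, and up to 4 members of a list called by camera or 2 of another. In the contrasts 4 features each way of at least that density are named, with the targeted and marker genes left out. The lists, made from general knowledge of yeast genes, are targeted genes, exosome and cofactors, TRAMP with Nrd1, Nab3 and Sen1, cytoplasmic 5' to 3' decay, nuclear 5' to 3' decay, Ski complex, nonsense-mediated decay, deadenylation, DEAD-box helicases, Nrd1 and Nab3 attenuated genes, ribosomal proteins, ribosome biogenesis, stress, sugar transport and use, glycolysis, respiration, phosphate, sulfur amino acids, Gcn4-controlled amino acids, purines, iron, meiosis, MATa, MATalpha, haploid genes, cell wall, histones, PAU genes, strain markers, mitochondrial genes, snoRNAs, RNA polymerase III, splicing and mRNA export. ARG5,6, ADE5,7, RPR1 and SCR1 were not matched. Alternative settings were recomputed for 335 pairs of a feature and a comparison, which are those the naming rule gives, apart from a gene the text does not name, and others the text could name. A first, smaller set left out list members whose direction reverses under rescaling, and it was widened after these values were seen.

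The method was tested on simulated data, with negative-binomial reads of a common dispersion drawn around group means, the mutant set to the mean of its control, and 200 features changed per draw in 20 draws. In the comparison of xrn1, over 9660 features, 50.2%, 65.5% and 87.0% of features changed 1.5-, 2- and 4-fold were called. For dbp2 (9657 features) these were 49.2%, 68.1% and 87.5%, and for tet-MTR4-Dox (9646 features) 52.4%, 68.2% and 87.0%. Among the calls 14.9%, 11.5% and 16.2% were unchanged features, more than the adjusted p of 0.05 implies, of which 72.4%, 82.1% and 83.3% lay below the median density, so calls of weak features are less certain. With voom weights the shares of unchanged features were 3.80%, 3.96% and 5.67%. These shares depend on how many features change, and in the data most features were called. They therefore do not carry over to the counts of calls below. A common factor of 3 left medians of 0.00527, 0.00740 and 0.00312 after rescaling, and camera called 2.5%, 3% and 2.5% of unchanged lists. Reads were drawn independently for each gene, so these shares do not cover lists whose genes vary together. In the data the estimated correlation of a class ran from 0.0128 to 0.783 on the spike-in scale, above the preset 0.01.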

Results

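RNA was measured in 10 libraries of budding yeast, Saccharomyces cerevisiae, in 5 groups of 2 biological replicates. A wild type (WT), a strain lacking XRN1 (xrn1) and a strain lacking DBP2 (dbp2) belong to the BY4741 background per the labels. In the BMA64-1A background, a wild type (WT-Dox) and a strain whose MTR4 gene is shut off by the antibiotic (tet-MTR4-Dox) were both kept in doxycycline at 10 µg/mL for 6 hours. Xrn1 is the main cytoplasmic 5' to 3' exoribonuclease, Dbp2 a DEAD-box RNA helicase, and Mtr4 the helicase that feeds RNA to the nuclear exosome. Total RNA without ribosomal RNA was sequenced by strand, and each library holds 16.0 M to 33.5 M reads counted on features, of which 1.35% to 3.14% fall on ERCC spike-in RNAs. For each ERCC read there were 33.5 and 35.2 yeast reads in WT, 72.4 and 72.8 in xrn1 and 41.4 and 43.6 in dbp2, against 30.8 and 32.0 in WT-Dox and 46.9 and 47.5 in tet-MTR4-Dox. These sums run over all feature rows, so a read shared by overlapping rows is counted in each of them. NUT and snoRNA rows, some sharing reads, held 4.46% and 5.40% of yeast reads in WT replicate 1. In tet-MTR4-Dox replicate 1 they held 12.5% and 14.1%. Values are the deposited normalized densities, so a fold change is a change per spike-in RNA, and a density is in arbitrary units.

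The targeted genes were read in every library first. XRN1 (YGL173C, chromosome VII, 175527 to 180113) had densities of 2.49 and 2.28 in WT and 0.102 and 0.106 in xrn1, 1.59 and 1.57 in dbp2, 1.32 and 1.20 in WT-Dox, and 1.89 and 1.87 in tet-MTR4-Dox. DBP2 (YNL112W, chromosome XIV, 413639 to 416281, 2 exons) had 3.49 and 3.41 in WT, 3.97 and 3.98 in xrn1, 0.00313 and 0.00326 in dbp2, 3.95 and 3.85 in WT-Dox, and 9.14 and 9.11 in tet-MTR4-Dox. MTR4 (YJL050W, chromosome X, 342522 to 345743) had 1.61 and 1.51 in WT, 2.35 and 2.37 in xrn1, 1.501 and 1.524 in dbp2, 1.49 and 1.30 in WT-Dox, and 0.429 and 0.469 in tet-MTR4-Dox. The log2 fold changes were -4.44 ± 0.06 (SE) for XRN1 in xrn1, -8.53 ± 0.05 for DBP2 in dbp2 and -1.62 ± 0.07 for MTR4 in tet-MTR4-Dox, with limma adjusted p-values of 1.5e-11, 1.1e-14 and 5.0e-09. DBP2 rose 2.34-fold in tet-MTR4-Dox (log2 1.23, or 0.38 relative to the median protein-coding gene), although its value lay below 0 once the libraries were rescaled on all features (-0.19) or on snoRNAs (-0.996). The snoRNAs themselves rose in tet-MTR4-Dox (median log2 2.15), so rescaling on them lowers every value of that comparison. XRN1 was at 0.663 of its WT level in dbp2 (log2 -0.59 ± 0.06, limma adjusted p = 8.9e-06).

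**Figure D1:**
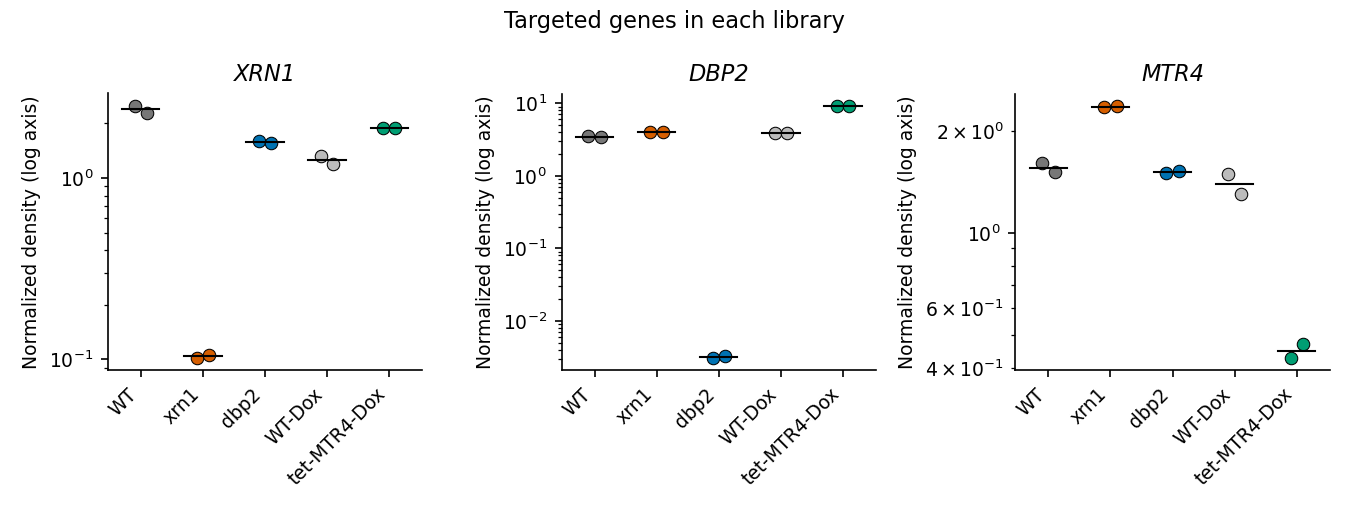
Normalized density (log axis) of XRN1, DBP2 and MTR4 in each of the 10 libraries, with points for the 2 libraries of a group and a line for their mean. Each gene is lowest in the group named for it: 0.102 and 0.106 for XRN1, 0.00313 and 0.00326 for DBP2, and 0.429 and 0.469 for MTR4.

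Marker genes of the strain genotypes differed between WT and dbp2 at more loci than DBP2. LYS2 (YBR115C, chromosome II, 469748 to 473926), a gene of lysine synthesis, had densities of 1.10 and 0.999 in WT but 0.000502 and 0.000349 in dbp2. MET17 (YLR303W, chromosome XII, 732542 to 733876), which makes homocysteine, had 0.00125 and 0.000477 in WT and none in xrn1, but 1.75 and 1.64 in dbp2. BY4741 is known to lack MET17 and to carry LYS2, so the dbp2 libraries differ from their control by these genes as well as by DBP2, and every dbp2 value below carries that difference. LEU2 and URA3 stayed at or below 0.00474 in all 6 libraries of WT, xrn1 and dbp2 and at 1.05 or more in the BMA64-1A libraries. TRP1 was at 0 and 0.000690 in WT-Dox and at 0.129 and 0.128 in tet-MTR4-Dox (0 and 1 reads against 104 and 143). The tet-MTR4-Dox libraries thus differ from their control at this marker as well as at MTR4. Every value of that comparison below carries the difference. MET17, which had reads in both groups, was at 7.87 and 7.68 in WT-Dox and at 1.36 and 1.53 in tet-MTR4-Dox. HIS3, ADE2 and CAN1 had reads in every library, and their log2 changes follow in the order xrn1, dbp2 and tet-MTR4-Dox. They were 2.64, 1.35 and 1.28 for HIS3, 1.76, 0.31 and 1.59 for ADE2, and 2.15, 0.74 and 0.94 for CAN1. Relative to the median protein-coding gene they were 0.73, 0.53 and 0.45, then -0.16, -0.50 and 0.76, then 0.24, -0.07 and 0.10.

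The comparison of xrn1 with WT asks which RNAs accumulate without Xrn1. Among protein-coding genes above the median density, the cell wall gene PIR3 (YKL163W, chromosome XI) rose 54.9-fold (log2 5.78 ± 0.12 SE, n = 2 libraries per group). SRL3, the vitamin B6 gene SNZ1 and the protein kinase gene KDX1 rose 50.4-, 49.1- and 46.3-fold, and MPC3, ATG41, TMA10 and RTS3 36.9- to 46.2-fold. Falls among these genes, apart from XRN1, were smaller: DDR48, a stress gene, went to 0.394 of its WT level (log2 -1.34 ± 0.09), YBR032W to 0.466, the alcohol dehydrogenase gene ADH1 to 0.638, and HUG1, a DNA damage response gene, to 0.657. TYE7, MXR1, PLS1 and TDH2 ended between 0.725 and 0.817, and the call of TDH2 (log2 -0.29) was lost without WT replicate 1 (-0.26, limma adjusted p = 0.065) or without xrn1 replicate 1 (-0.26, adjusted p = 0.061).

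Noncoding RNAs rose with them. XUTs, the lncRNAs named in earlier work for their rise without Xrn1, were higher in 1447 of the 1452 measured and lower in 0, and since the class was chosen on that response, its rise is not independent evidence. The median XUT rose by 2.47 on the log2 scale (replicate pairs 2.45 to 2.52), and XUT0575, XUT1472, XUT0566 and XUT0599 rose 51.6-, 48.8-, 46.7- and 44.0-fold. CUTs, unstable transcripts named for their rise without nuclear exosome activity, had a median of 1.27, with CUT229, CUT540 and CUT281 up 40.5-, 28.9- and 18.6-fold, while CUT287 and CUT437 went to 0.397 and 0.419 of WT. NUTs, transcripts named for their rise without Nrd1, had a median of 1.78, and NUT1303, NUT0453 and NUT1459 rose 74.2-, 49.6- and 44.1-fold, of which NUT1459 shares its reads with ATG41. Small nucleolar RNAs (snoRNAs) had a median of -0.11, with 14 of 76 higher and 20 lower (14 higher and 13 lower adjusted over the list alone), and snR36, snR67, snR128 and snR41 at 0.494, 0.595, 0.605 and 0.613 of WT. The call of snR41 was lost without WT replicate 2 (log2 -0.63) or without xrn1 replicate 2 (-0.39).

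Across all 9666 features, 9181 were higher and 84 lower in xrn1 by limma at an adjusted p under 0.05. The lower count ranged from 49 without xrn1 replicate 2 to 105 without xrn1 replicate 1. The median protein-coding gene rose by 1.90, and rescaled on the protein-coding genes the split became 4066 higher and 3188 lower. Changes called relative below are on that rescaled basis. Relative to that median, 904 XUTs were higher and 92 lower, 173 CUTs higher and 335 lower, 525 NUTs higher and 248 lower, and all 76 snoRNAs lower. The XUT median exceeded the protein-coding median by 0.57 (replicate pairs 0.55 to 0.62). Set against protein-coding genes matched on density in WT-Dox, the excess was 0.10 (95% bootstrap interval -0.06 to 0.28). Against all protein-coding genes, but with a pseudocount 4 times larger, it was 0.01. The NUT median lay 0.12 below the protein-coding one (-0.12), and above it with a pseudocount 4 times smaller (0.15), on the protein-coding basis (0.20) or with voom (0.26). Camera placed XUTs apart from other features after rescaling (p = 5.2e-10, and p = 0.0440 with an estimated correlation) and with voom on the spike-in scale (p = 0.0188), but not with log2 densities on that scale (p = 0.729).

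Gene lists fixed in advance moved apart in xrn1. Of 138 cytosolic ribosomal protein genes, 128 rose per spike-in RNA and 0 fell, but relative to the median protein-coding gene 3 were higher and 133 lower (camera adjusted p = 1.1e-26 for a smaller rise, and adjusted p = 0.359 with an estimated correlation). Of 18 glycolytic genes 11 rose and 2 fell, ADH1 and TDH2, and 16 were lower in relative terms (adjusted p = 7.3e-25, and adjusted p = 0.107 with an estimated correlation). Ribosome biogenesis genes rose in 74 of 76 cases, with 71 lower in relative terms (adjusted p = 0.0018, and adjusted p = 0.970 with an estimated correlation). Phosphate regulon genes rose in 16 of 19, with 13 lower in relative terms (adjusted p = 0.00021, and adjusted p = 0.691 with an estimated correlation), and all 10 histone genes rose and were lower in relative terms (adjusted p = 0.366, or 0.00068 after rescaling and 0.295 with an estimated correlation). The list of snoRNAs kept its call with an estimated correlation against protein-coding genes (adjusted p = 0.0378), but not against all features (0.146) or after rescaling (0.384).

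Further lists were called on the spike-in scale. All 39 Gcn4-controlled amino acid genes rose, led by SER3 (21.6-fold, serine synthesis) and the arginine genes ARG1, ARG3 and ARG4 (18.5-, 18.2- and 14.4-fold), with 15 higher and 20 lower in relative terms (21 lower adjusted over the list alone). Camera called that list upward (adjusted p = 0.0294, and adjusted p = 0.970 with an estimated correlation) although its relative median was -0.10 and its relative mean 0.17. All 49 nuclear genes of respiration rose, with 24 higher and 15 lower in relative terms and CYC7, NDI1 and SDH1 up 14.6-, 10.1- and 9.84-fold (adjusted p = 0.0064, and adjusted p = 0.970 with an estimated correlation). All 33 measured meiotic genes rose and 18 were higher and 3 lower in relative terms, at a relative median of 0.51, yet camera on the spike-in scale ranked them below other genes (adjusted p = 0.00084, and adjusted p = 0.107 with an estimated correlation). Camera ranks moderated t values, so a list of imprecise genes can take the opposite sign to its median. The iron genes FRE2 and MRS4 rose 30.4- and 15.3-fold, the methionine genes MET1 and MUP3 19.0- and 15.9-fold, the subtelomeric PAU7 and PAU12 17.3- and 15.7-fold, and MAL11 and FLO10 26.9- and 23.9-fold. Members of those families that are near-identical copies, as PAU genes are, may share reads and are uncertain.

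The comparison of dbp2 with WT asks the same of Dbp2. HSP12 (YFL014W, chromosome VI), a membrane stress protein gene, rose 351-fold (log2 8.46 ± 0.10 SE, n = 2 libraries per group), DDR2, a further stress gene, 282-fold, and COX26 83.3-fold. NCA3, PIR3, FMP16 and RTC3 rose 52.2-, 50.8-, 43.3- and 32.8-fold. CUP1-1, a metallothionein gene with a near-identical copy, had a log2 change of 7.53 with an SE of 1.48 and is uncertain. Among genes of at least the median density, DBP2 and LYS2 aside, the largest falls were in phosphate regulon genes: PHO84 (YML123C, chromosome XIII), the high-affinity transporter, to 0.0072 of WT (log2 -7.12 ± 0.10), PHO12 to 0.0445, PHM6 to 0.0746, SPL2 to 0.0752 and VTC3 to 0.146. BAR1, a pheromone protease gene, and the methionine and histidine genes MET6 and HIS4 went to 0.194, 0.233 and 0.245.

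XUTs were higher in 1263 and lower in 16 of 1452, at a median of 1.25 (replicate pairs 1.22 to 1.30). XUT0788, XUT0427, XUT0586 and XUT1395 rose 28.4-, 14.7-, 14.0- and 13.9-fold. CUT and NUT medians were 1.16 and 1.10, with CUT122, CUT172 and CUT324 up 248-, 14.4- and 13.9-fold and NUT0227, NUT0604 and NUT0034 350-, 26.5- and 24.2-fold. NUT0227 carries the reads of HSP12 in every library, so its value is that of HSP12. Of the snoRNAs, 63 were higher and 4 lower at a median of 0.79, with snR78 and snR52 up 6.81- and 5.38-fold and snR8 at 0.336 of WT. NUT1082 went to 0.318.

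In all, 8201 features were higher and 514 lower, and the median protein-coding gene rose by 0.81. Rescaled on protein-coding genes the split was 4322 higher and 2645 lower, with 817 XUTs higher and 126 lower, 437 CUTs higher and 58 lower, 669 NUTs higher and 100 lower, and 20 snoRNAs higher and 21 lower. The XUT median exceeded the protein-coding median by 0.45 (replicate pairs 0.42 to 0.49). Against protein-coding genes matched on density in WT-Dox, however, XUTs rose less, by a difference of -0.28 (95% bootstrap interval -0.46 to -0.12). With a pseudocount 4 times larger the XUT excess of 0.45 became 0.089, the CUT excess of 0.35 became 0.00169 and the NUT excess of 0.30 became -0.09. Camera separated XUTs from other features after rescaling (p = 7.5e-06, and p = 0.112 with an estimated correlation), not on the spike-in scale (p = 0.741).

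Several lists of metabolic genes ranked low in dbp2, some of them falling per spike-in RNA and others only in relative terms. Of 19 phosphate regulon genes 14 fell and 5 rose (3 higher and 16 lower in relative terms, camera adjusted p = 4.7e-21, and adjusted p = 0.256 with an estimated correlation). Of 18 glycolytic genes 12 fell and 4 rose (0 higher and 16 lower in relative terms), with TDH2, ADH1, HXK2 and ENO2 at 0.251, 0.273, 0.288 and 0.298 of WT (adjusted p = 2.1e-20, and adjusted p = 0.256 with an estimated correlation). Purine synthesis genes fell in 10 of 15 and rose in 5, with 14 lower in relative terms, and ADE17, ADE3 and ADE6 went to 0.268, 0.458 and 0.482 (adjusted p = 4.9e-12, and adjusted p = 0.374 with an estimated correlation). Gcn4-controlled amino acid genes were split, 17 up and 18 down (7 higher and 31 lower in relative terms), with HIS1, ILV6 and ASN2 at 0.512, 0.569 and 0.611, at a median of -0.05 and a mean of 0.10 (adjusted p = 8.0e-11, and adjusted p = 0.812 with an estimated correlation). Sulfur amino acid genes rose in 12 and fell in 9 of 24, with 8 higher and 14 lower in relative terms and SAM2, MET5 and CYS3 at 0.316, 0.426 and 0.449, at a median of 0.14 that lies above 0 while the test points down (adjusted p = 1.0e-06, and adjusted p = 0.807 with an estimated correlation). In that pathway MET17 itself is a marker that differs between the strains.

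Ribosomal protein genes rose in 93 and fell in 18 of 138, and relative to the median gene 9 were higher and 112 lower (10 higher and 112 lower adjusted over the list alone), with RPL8A and RPL9B, each of which has a near-identical copy, at 0.357 and 0.460 of WT (adjusted p = 0.0021, and adjusted p = 0.976 with an estimated correlation). The 44 splicing factor genes all rose, 25 higher and 4 lower in relative terms (3 lower adjusted over the list alone), led by MSL1 and SMX2 at 3.78- and 3.65-fold (adjusted p = 0.0128, and adjusted p = 0.976 with an estimated correlation). Nuclear genes of respiration rose in 47 of 49 and fell in 1, 29 higher and 14 lower in relative terms, with CYC7 and ATP14 at 13.6- and 4.66-fold (adjusted p = 0.0167, and adjusted p = 0.976 with an estimated correlation). Stress genes rose in 39 of 49 and fell in 8 (29 higher and 15 lower in relative terms, camera adjusted p = 0.901), and meiotic genes rose in 30 of 33 and fell in 1 (24 higher and 3 lower in relative terms, adjusted p = 0.564, or 0.00075 after rescaling and 0.228 with an estimated correlation), with SPS100 and RIM4 at 17.9- and 12.0-fold. HO, the mating-type endonuclease gene, went to 0.0656 of WT.

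The comparison of tet-MTR4-Dox with WT-Dox asks which RNAs accumulate when Mtr4 is depleted. The noncoding classes rose furthest. CUT307, CUT222 and CUT676 rose by 10.37 ± 0.16, 10.23 ± 0.24 and 10.08 ± 0.21 on the log2 scale (SE, n = 2 libraries per group), XUT1358, XUT0649, XUT1083 and XUT0766 151-, 104-, 87.4- and 81.5-fold, and NUT0304, NUT0942 and NUT0349 93.6-, 90.0- and 89.5-fold. Replicates of tet-MTR4-Dox differed most, with a chi-square of recovered reads per degree of freedom of 9.57 against 3.32 to 4.75 in other groups. The SEs, pooled over all groups, may understate the spread here. The medians were 4.32 for CUTs, 3.58 for NUTs and 2.82 for XUTs (replicate pairs 2.78 to 2.87), against 0.84 for protein-coding genes. CUT648 and XUT0788 fell, to 0.332 and 0.490 of WT-Dox. All 76 snoRNAs rose, at a median of 2.15, with snR58, snR48, snR56 and snR53 at 105-, 75.4-, 67.7- and 58.5-fold. CUTs and NUTs were named in earlier work for their rise without nuclear decay or termination factors, so their rise here is not independent of that choice.

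Among protein-coding genes YDR042C rose 118-fold (log2 6.89 ± 0.14), DDR2 46.1-fold, HSP12 41.7-fold and HEM4, a heme synthesis gene (YOR278W, chromosome XV), 38.6-fold. YJL047C-A, FLX1, YNL042W-B and the chaperone gene HSP26 rose 36.5-, 32.1-, 25.7- and 25.5-fold. The acid phosphatase genes PHO5 (YBR093C, chromosome II) and PHO12 went to 0.0645 and 0.0890 of WT-Dox, PHM6 to 0.120, PHO84 to 0.321, ARG1 to 0.234, MET6 to 0.273, ADH1 to 0.291 and SFG1 to 0.338. NRD1, which encodes a termination factor for short noncoding RNAs, rose 10.7-fold, and MPP6 and RRP46, genes of the exosome and its cofactors, 3.13- and 2.66-fold, although these last genes had values below 0 when the libraries were rescaled on snoRNAs (log2 -0.56 and -0.80). The snoRNAs rose in 76 of 76 cases at a median of 2.15, so rescaling on them lowers every gene. Values below 0 on that basis in tet-MTR4-Dox, here and below, mean a smaller change than that of the median snoRNA.

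In all, 8825 features were higher and 316 lower. Rescaled on protein-coding genes the split was 6039 and 2371, and rescaled on snoRNAs it was 3227 and 5437. As the snoRNAs themselves rose, that last split counts changes against their rise. On the protein-coding basis 1372 XUTs were higher and 12 lower (1430 and 1 per spike-in RNA), 862 CUTs higher and 9 lower (882 and 1), 1207 NUTs higher and 9 lower (1232 and 0), and 70 snoRNAs higher and 2 lower. The XUT median exceeded the protein-coding one by 1.98 (replicate pairs 1.88 to 2.10), and by 0.83 against protein-coding genes matched on density in WT (95% bootstrap interval 0.67 to 0.97). With a pseudocount 4 times larger it was 1.31. Camera placed XUTs above other features (p = 0.00014, and p = 0.0998 with an estimated correlation), and after rescaling (p = 1.2e-14, and p = 0.0209 with an estimated correlation). Adjusted over the classes tested, that last camera p was 0.0438.

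**Figure D2:**
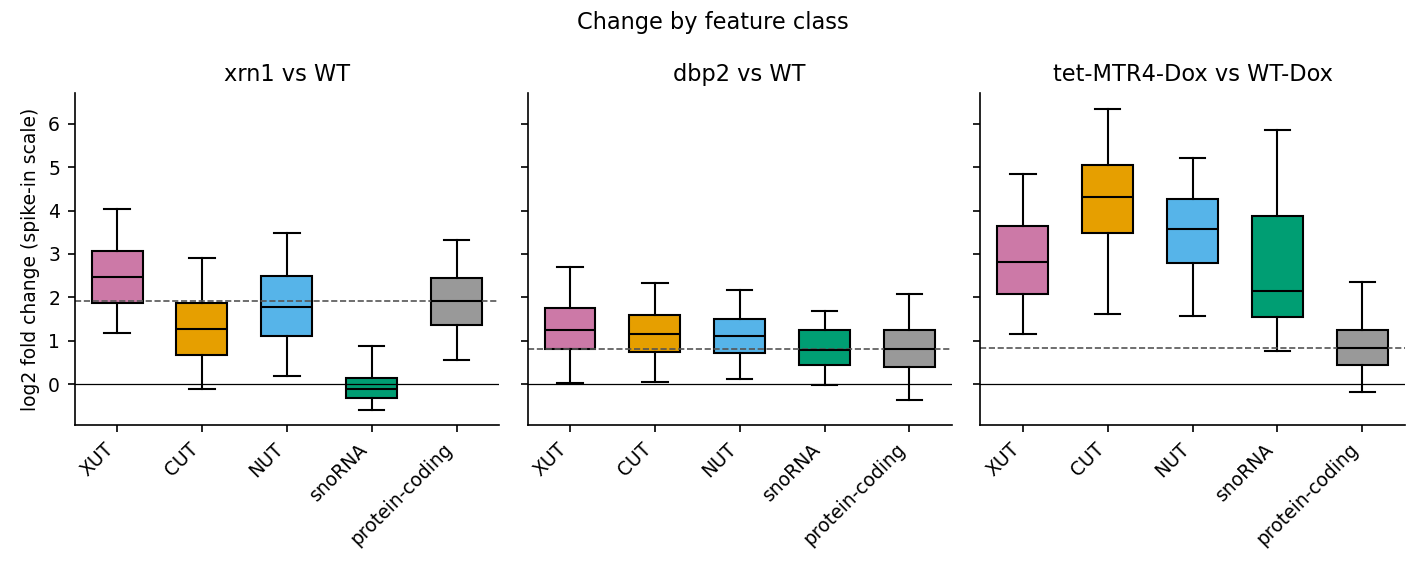
Distribution of log2 fold changes per spike-in RNA in 5 feature classes and 3 comparisons, with boxes for quartiles, whiskers from the 5th to the 95th percentile, and a dashed line at the protein-coding median. CUT medians are 1.27, 1.16 and 4.32 in xrn1, dbp2 and tet-MTR4-Dox, while snoRNA medians are -0.11, 0.79 and 2.15.

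Several lists ranked low with Mtr4 depletion, where phosphate, glycolytic and sulfur genes had medians below 0 per spike-in RNA (-0.64, -0.48 and -0.20) and Gcn4-controlled and ribosomal protein genes medians of 0.01. Of 19 phosphate regulon genes 12 fell and 3 rose (2 higher and 17 lower in relative terms), PHO11 going to 0.129 (camera adjusted p = 2.1e-27, and adjusted p = 0.224 with an estimated correlation). Of 18 glycolytic genes 14 fell and 3 rose (3 higher and 15 lower in relative terms), with TDH2, PGK1 and ENO2 at 0.341, 0.394 and 0.543 (adjusted p = 3.4e-27, and adjusted p = 0.224 with an estimated correlation). Sulfur amino acid genes fell in 13 and rose in 9 of 24 (3 higher and 18 lower in relative terms), with SAM3, SAM2 and MUP1 at 0.474, 0.487 and 0.501 (adjusted p = 8.8e-19, and adjusted p = 0.339 with an estimated correlation). Gcn4-controlled genes fell in 16 and rose in 13 of 39 (13 higher and 15 lower adjusted over the list alone, and 4 higher and 35 lower in relative terms), with ARG3 and HOM2 at 0.334 and 0.671 (adjusted p = 2.0e-15, and adjusted p = 0.731 with an estimated correlation). Ribosomal protein genes rose in 43 and fell in 37 of 138 (40 and 36 adjusted over the list alone, and 4 higher and 130 lower in relative terms), with RPL3, RPS3 and RPL4B at 0.532, 0.629 and 0.638 (adjusted p = 1.7e-33, and adjusted p = 0.358 with an estimated correlation). Histone genes rose in 3 and fell in 4 of 10 (2 and 4 adjusted over the list alone), all 10 were lower in relative terms, and HHT2 and HHO1 were at 0.766 and 0.787 (adjusted p = 9.3e-08, and adjusted p = 0.358 with an estimated correlation).

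Counts of further lists follow. Purine genes rose in 12 and fell in 1 of 15 (10 higher and 5 lower in relative terms, camera adjusted p = 0.535), with MTD1 and ADE17 at 6.37- and 5.87-fold. Meiotic genes rose in 31 and fell in 1 of 33 (27 higher and 1 lower in relative terms, camera adjusted p = 0.449, or 9.8e-05 after rescaling and 0.205 with an estimated correlation), REC104 and SPO20 reaching 52.2- and 9.45-fold. The pheromone gene MFA1 rose 10.1-fold, and FLO1 and PIR3 13.7- and 23.4-fold. The 44 splicing factor genes rose, with 28 higher and 7 lower in relative terms and SYF2 and MUD1 at 3.82- and 3.69-fold (adjusted p = 0.0220, and adjusted p = 0.910 with an estimated correlation), although SYF2 and MUD1 had values below 0 when the libraries were rescaled on snoRNAs (-0.23 and -0.29). Ribosome biogenesis genes rose in 75 and fell in 1 of 76, with 29 higher and 26 lower in relative terms (25 lower adjusted over the list alone; adjusted p = 0.0220, and adjusted p = 0.910 with an estimated correlation). The snoRNA list was called upward (adjusted p = 1.2e-07, and adjusted p = 0.910 with an estimated correlation). Genes encoded in mitochondria rose in 4 and fell in 1 of 8, ATP6 going to 0.696, with 6 lower in relative terms, and were called downward (adjusted p = 0.0233, and adjusted p = 0.910 with an estimated correlation), a call lost without WT-Dox replicate 1, tet-MTR4-Dox replicate 1 or either xrn1 library.

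**Figure D3:**
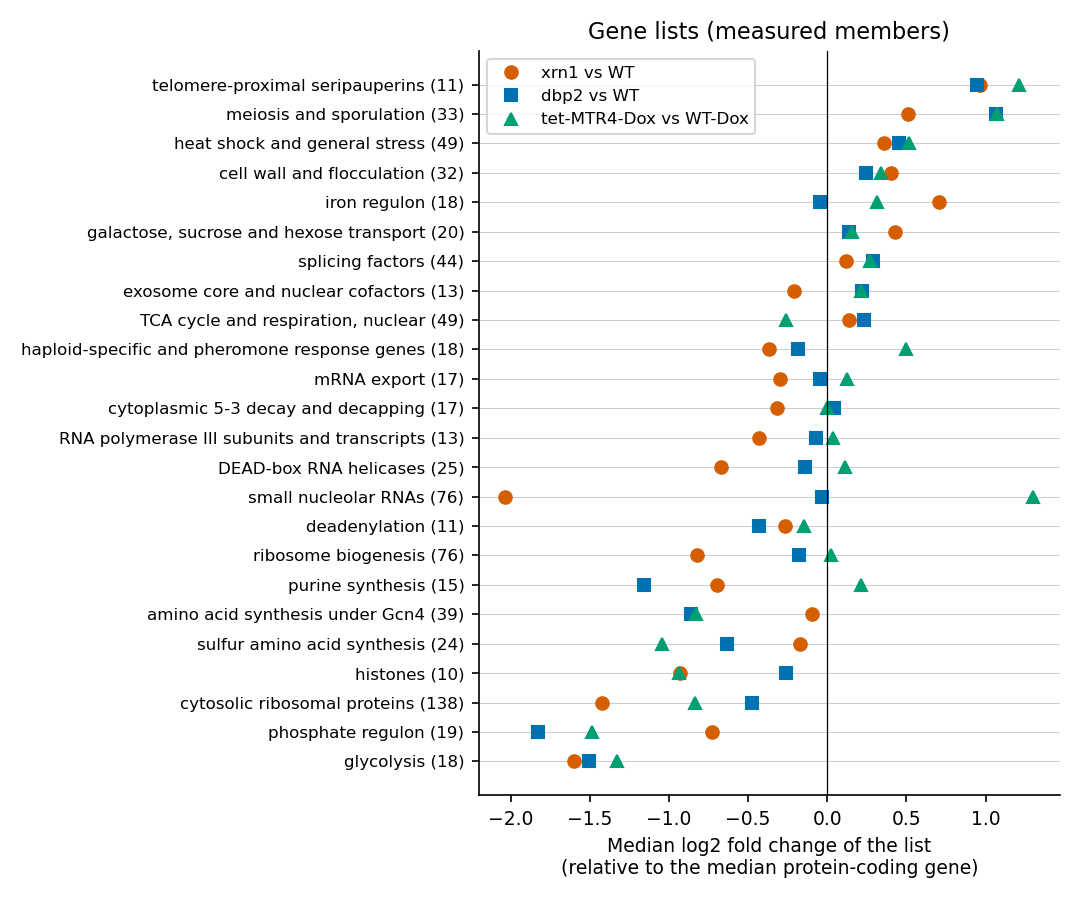
Median log2 fold change of each gene list with at least 10 measured members, relative to the median protein-coding gene, in the 3 comparisons (number of measured members in brackets). Glycolytic genes lie below 0 in each comparison, with 1, 0 and 3 members higher and 16, 16 and 15 lower, while snoRNAs lie at -2.03, -0.03 and 1.30.

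Genes of RNA decay and processing were counted in the same way. In the order xrn1, dbp2 and tet-MTR4-Dox, exosome and cofactor genes rose in 13, 13 and 13 of 13 (relative 1 higher and 7 lower, 9 and 3, 8 and 0). The 7 genes of TRAMP and of Nrd1, Nab3 and Sen1 rose in 7, 5 and 7 (relative 3 and 4, 1 and 3, 4 and 2). Decapping and cytoplasmic 5' to 3' decay genes rose in 17, 14 and 17 of 17 (relative 7 and 9, 8 and 8, 7 and 6), where EDC1 rose 13.9-fold in xrn1 and DCS2 8.67-, 9.78- and 3.26-fold, although DCS2 in tet-MTR4-Dox lay below 0 rescaled on snoRNAs (log2 -0.35). Nuclear 5' to 3' decay genes rose in 3, 3 and 3 of 3 (relative 0 and 2, 2 and 1, 2 and 1), Ski complex genes in 4, 3 and 4 of 4 (relative 0 and 3, 1 and 3, 2 and 2), genes of nonsense-mediated decay in 4, 4 and 4 of 4 (relative 1 and 0, 2 and 1, 2 and 1), and deadenylation genes in 11, 8 and 11 of 11 (relative 5 and 6, 1 and 8, 2 and 5). DEAD-box helicase genes rose in 25, 19 and 20 of 25 and fell in 0, 5 and 1 (relative 5 and 19, 7 and 13, 12 and 9), where those lower in dbp2 include the deleted DBP2 itself. RNA polymerase III genes rose in 13, 12 and 13 of 13 (relative 2 and 9, 2 and 5, 5 and 4), mRNA export genes in 17, 14 and 16 of 17 (relative 3 and 11, 7 and 7, 7 and 6), MTR2 and YRA1 being up 10.1- and 9.99-fold in xrn1, and splicing factor genes in 44 of 44 in xrn1 (relative 19 and 12). On the spike-in scale camera called none of these in xrn1, with adjusted p-values of 0.0628 to 0.951, and among them only splicing factors in dbp2 and tet-MTR4-Dox. After rescaling it also called DEAD-box helicase genes downward in xrn1 (adjusted p = 0.0034, and adjusted p = 0.295 with an estimated correlation) and exosome and cofactor genes upward in tet-MTR4-Dox (adjusted p = 0.0306, and adjusted p = 0.240 with an estimated correlation). The 8 genes attenuated by Nrd1 and Nab3 rose in 7, 3 and 8 and fell in 1, 4 and 0 (relative 2 and 6, 1 and 6, 6 and 2; adjusted p = 0.0440, 0.00055 and 0.109, and adjusted p = 0.871, 0.807 and 0.910 with an estimated correlation). Of these IMD2, which encodes IMP dehydrogenase, was at 0.835 and 0.788 of WT in xrn1 and dbp2.

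Adjusted over the list alone, the spike-in counts differed from those over all features for 1 list in xrn1 (snoRNAs), no list in dbp2 and 4 lists in tet-MTR4-Dox, of which mitochondrial genes (3 higher and 1 lower) were the remaining list. Stress genes rose in 47 and 42 of 49 and fell in 1 and 4 in xrn1 and tet-MTR4-Dox (relative 26 and 15, 29 and 16; camera adjusted p = 0.856 and 0.457). In the order xrn1, dbp2 and tet-MTR4-Dox, genes of sugar transport and use rose in 20, 15 and 16 of 20 (relative 12 and 6, 9 and 7, 9 and 7), iron genes in 18, 13 and 14 of 18 (relative 11 and 4, 8 and 9, 10 and 7), cell wall genes in 31, 25 and 26 of 32 (relative 20 and 9, 16 and 14, 19 and 11), and PAU genes in 11, 10 and 10 of 11 (relative 8 and 0, 9 and 0, 10 and 0). MATa genes rose in 6, 4 and 5 of 7 (relative 1 and 6, 1 and 5, 3 and 3), and MATalpha genes, markers of the other mating type, in 1, 2 and 2 of the 2 measured (relative 1 and 1, 0 and 0, 2 and 0). Haploid and pheromone genes rose in 16, 13 and 16 of 18 (relative 4 and 13, 7 and 9, 10 and 5), while HO was at 0.277, 0.0656 and 0.162 of its control. Purine and sulfur amino acid genes rose in 14 of 15 and 23 of 24 in xrn1 (relative 2 and 12, 7 and 12), and respiration genes in 39 of 49 in tet-MTR4-Dox (relative 12 and 29). Histone genes rose in 9 of 10 in dbp2 (relative 3 and 6), ribosome biogenesis genes in 68 of 76 (relative 20 and 44), and mitochondrial genes in 6 and 7 of 8 in xrn1 and dbp2 (relative 0 and 8, 2 and 1). Strain markers rose in 5, 6 and 4 of 8 (relative 2 and 2, 3 and 2, 4 and 4), and the 3 targeted genes rose in 2, 0 and 2 and fell in 1, 2 and 1 (relative 0 and 3, 0 and 3, 1 and 2).

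Of these remaining lists, camera placed several below other genes in xrn1, on the spike-in scale and not with an estimated correlation. They were the mitochondrial genes (adjusted p = 7.1e-07, and adjusted p = 0.365 with an estimated correlation), the haploid genes (adjusted p = 0.0033, and adjusted p = 0.691 with an estimated correlation) and the MATa genes (adjusted p = 0.0440, and adjusted p = 0.691 with an estimated correlation). Among them VAR1, a mitochondrial ribosomal protein gene, went to 0.607 in xrn1, a call lost without WT replicate 1, xrn1 replicate 2 or either dbp2 library. The lists of targeted genes and strain markers hold genes that are deleted or absent by genotype, which fixes part of their camera results, and these are not given. The MATa call in xrn1 was lost without WT replicate 1 or either library of xrn1 or tet-MTR4-Dox, the Gcn4 call without WT replicate 1, and the call of Nrd1 and Nab3 attenuated genes without WT replicate 2 or either xrn1 library.

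Rescaling on protein-coding genes changed other calls of camera as well. In xrn1 purine genes were then called downward (adjusted p = 0.0074) and PAU genes upward (0.0368), while the calls of respiration (0.249), Gcn4-controlled (0.808), meiotic (0.0853), MATa (0.0889), haploid (0.157) and Nrd1 and Nab3 attenuated genes (0.108) were lost. In dbp2 the calls of Nrd1 and Nab3 attenuated (0.0642), respiration (0.0655) and sulfur amino acid genes (0.0772) were lost. In tet-MTR4-Dox stress and PAU genes were called upward (0.0473 and 0.0225) and respiration genes downward (0.0393), and the calls of ribosome biogenesis (0.584) and mitochondrial genes (0.0934) were lost. With an estimated correlation no list was called after rescaling, the lowest adjusted p-values of camera being 0.295, 0.228 and 0.205.

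Other single members of the lists follow, taken by the size of their change. Values below 0 after rescaling are given for their direction, and not all of them pass the limma threshold. In xrn1 RRP42 and RRP40 of the exosome rose 4.25- and 4.14-fold, AIR2 and NRD1 6.79- and 5.21-fold, EBS1 of nonsense-mediated decay 5.43-fold, and the deadenylation genes PAN3 and PUF3 5.70- and 5.33-fold. The helicase genes DHH1 and DBP7 rose 5.42- and 4.83-fold, MAF1 and RPC25 of the RNA polymerase III list 5.96- and 5.64-fold, and the splicing genes PRP16 and MUD2 8.59- and 8.34-fold. SOL4, MTH1, QCR9, MTD1, ADE8 and SAG1 rose 17.6-, 9.78-, 9.05-, 5.59-, 4.57- and 15.2-fold. RTT103, RAI1, SKI8 and the histone genes HTZ1 and HHF2 rose 3.51-, 3.37-, 3.15-, 2.41- and 2.35-fold per spike-in RNA, but lay below the median protein-coding gene (relative log2 -0.083, -0.15, -0.26, -0.64 and -0.69). SKI7 and UPF3 rose 3.92- and 3.95-fold and lay below 0 only when rescaled on all features (-0.053 and -0.049).

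In dbp2 MPP6 and RRP46 rose 3.13- and 3.04-fold, AIR2 2.27-fold, EDC2 5.11-fold, RAI1 and RTT103 2.60- and 2.04-fold, SKI7 2.18-fold, UPF3 and NMD2 2.51- and 2.09-fold, and CDC36 2.42-fold. RRP3 and FAL1 rose 3.04- and 2.72-fold, BUD21 and IMP3 each 3.03-fold, MAF1 and RPC19 2.46- and 2.23-fold, PRP21 and LEA1 each 3.49-fold, MTR2 and THP1 3.37- and 3.07-fold, and the histone genes HTB1 and HHF1 2.22- and 2.16-fold. HXT5 and HXT8, which carry hexoses, rose 12.6- and 3.97-fold, SDH2 and QCR9 3.46- and 3.44-fold, HMX1 and FIT1 3.86- and 3.84-fold, and PRM10, CWP2, PAU10, PAU12, MFA1, VAR1 and COX3 8.46-, 4.801-, 5.10-, 4.85-, 2.58-, 3.92- and 2.08-fold. ADE12, URA2 and IMD3 were at 0.578, 0.753 and 0.829 of WT, and RPL7B and RPP0 each at 0.723. SKI8 and CAF40 rose 1.46- and 1.72-fold but lay below the median protein-coding gene (relative log2 -0.27 and -0.027), SKI8 also below 0 on snoRNAs (-0.15). TRF5, SAG1 and MF(ALPHA)2 rose 1.87-, 1.77- and 1.57-fold and lay below 0 rescaled on all features (-0.082, -0.15 and -0.0067). The call of MF(ALPHA)2 was lost without WT replicate 2, dbp2 replicate 1 or dbp2 replicate 2, where its log2 change ranged from 0.32 to 0.69 (limma adjusted p = 0.251 to 0.0666).

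In tet-MTR4-Dox MAL11 and GAL3 rose 5.08- and 4.27-fold, FRE2 and HMX1 6.35- and 5.76-fold, CYC7, MF(ALPHA)2 and PRM10 12.1-, 8.58- and 5.46-fold, and PAU10 and PAU12 10.2- and 6.33-fold, while RPP0, HHF2 and HTA1 went to 0.652, 0.802 and 0.838. Other members rose per spike-in RNA and relative to the median protein-coding gene, but lay below 0 rescaled on snoRNAs. These were AIR2 and EDC1 (3.39- and 4.44-fold, -0.42 and -0.038 on snoRNAs), GSC2 (4.56-fold, -0.0099), PRP5 and FAL1 (each 2.72-fold, -0.70 and -0.75), and UTP20, RPF1 and NOP15 (3.06-, 2.82- and 2.72-fold, -0.60, -0.72 and -0.77). The same held for MSL1 and SMD3 (3.597- and 3.23-fold, -0.33 and -0.51), NAB2 and THO2 (3.73- and 3.17-fold, -0.32 and -0.54), QCR9 (2.67-fold, -0.80), and MFA2 and SAG1 (log2 1.58 and 1.45, -0.64 and -0.69). Below 0 on snoRNAs and also on all features were RTT103 and RAI1 (2.501- and 2.205-fold, -0.064 and -0.26 on all features), SKI7 and SKI3 (2.36- and 2.00-fold, -0.15 and -0.40), UPF3 and NMD2 (2.55- and 2.42-fold, -0.042 and -0.12), CDC39 and CDC36 (2.21- and 2.07-fold, -0.27 and -0.35), IMP3 (2.64-fold, -0.0088), and RPC34 and RPC19 (each 2.36-fold, -0.17 and -0.18).

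The overlap of XUTs between dbp2 and tet-MTR4-Dox addresses whether the same lncRNAs accumulate without either helicase. XUTs called higher in both numbered 1246 of 1452, where independent lists of 1263 and 1430 would share 1243.9. In relative terms 785 were higher in both against 772.0 for independent lists (ratio 1.02). At 2-fold or more these were 894 against 889.6 per spike-in RNA and 385 against 365.1 in relative terms. With 1430 XUTs called in tet-MTR4-Dox, or 1372 in relative terms, the ratio without a fold limit was held near 1 in advance. At 2-fold or more 1395 XUTs were called there per spike-in RNA, which held that ratio near 1 too. In relative terms they numbered 1233 at 2-fold, which left the ratio little room. Odds ratios were 1.99 and 1.39 at 2-fold per spike-in RNA (one-sided Fisher p = 0.147 and 0.140). In relative terms they were 2.01 and 1.75 (Fisher p = 0.0019 and 0.00071). These p-values treat XUTs as independent and are descriptive. All 3 comparisons called 1243 XUTs higher, or 584 in relative terms. XUT0788 went against this, up 28.4-fold in dbp2 and at 0.490 in tet-MTR4-Dox. Across the 1452 XUTs, which are not independent replicates, the log2 changes in dbp2 and tet-MTR4-Dox had a Pearson correlation of 0.0556 (Spearman 0.0416), against 0.613 (Spearman 0.685) across 5613 protein-coding genes and 0.378 across all features. These comparisons share no library.

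**Figure D4:**
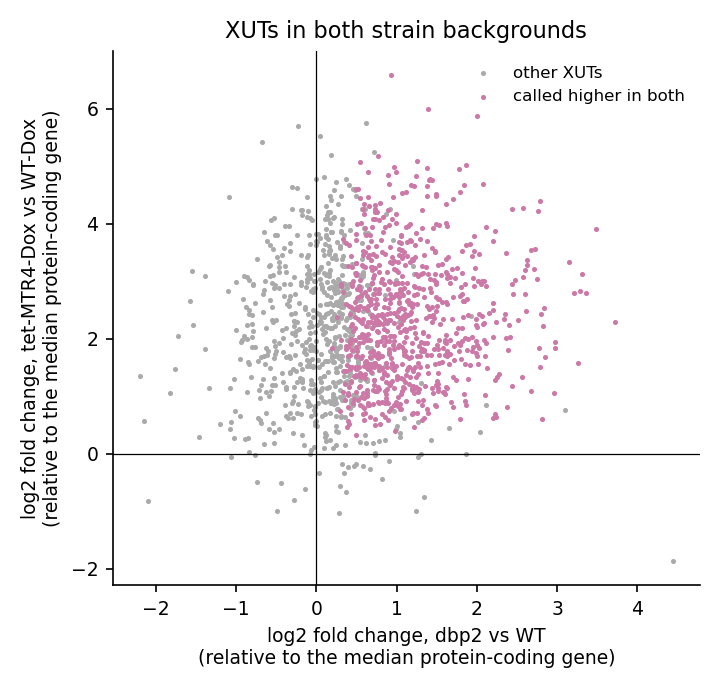
Log2 fold changes of the 1452 XUTs in dbp2 (horizontal) and in tet-MTR4-Dox (vertical), relative to the median protein-coding gene, with the 785 XUTs called higher in both in colour. Most points lie above 0 on the vertical axis, and on the spike-in scale the Pearson correlation is 0.0556.

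The comparisons of xrn1 and dbp2 use the same WT libraries. They called 1260 XUTs higher in both (1258.7 for independent lists), and 606 in relative terms against 508.7. Simulations of unchanged groups gave 0, which their lack of any change sets in advance. The correlation across all features was 0.394. Unchanged groups gave 0.500 against the same controls, a value that follows from noise with shared controls and is no standard for changed groups. The covariance was 0.314 against a simulated 0.0114. Across XUTs the covariance was 0.216 against a simulated 0.0206. In these simulations the shared controls thus gave only a small part of the covariance. Part of any excess in the overlap of calls may still come from them. A split of the WT libraries, which would leave a single library for each comparison, was not run. For xrn1 and tet-MTR4-Dox the correlation was -0.00483 across all features, -0.247 across XUTs and 0.391 across protein-coding genes. XUTs called higher in both of these numbered 1425 (1425.1 for independent lists), or 861 in relative terms against 854.2. Most XUTs were called in xrn1 (1447) and in tet-MTR4-Dox (1430, or 1372 in relative terms). That holds the counts of 1260, 1425 and 861 near those of independent lists.

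Compared directly, 7440 features were higher and 826 lower in xrn1 than in dbp2, or 3358 and 3812 in relative terms. Features named in these contrasts are of at least the median density, with the targeted and marker genes left out. PHO84, SPL2, TPO4 and HIS4 were 272-, 47.9-, 25.7- and 22.4-fold higher in xrn1, while HSP12 was at 0.0432 and the copies CUP1-1 and CUP1-2 at 0.0228 and 0.0409 of their dbp2 level. The dbp2 effect exceeded the MTR4 effect at 1486 features and fell short of it at 5049 (1784 and 5150 in relative terms, 6024 and 2218 rescaled on snoRNAs). After CUP1-1, the largest named differences in the former were in FMP16, YGP1 and COX26, with values of 3.37, 3.21 and 3.13 on the log2 scale, and in the latter those of CUT307, CUT342, CUT676 and CUT681, with -9.10, -8.35, -8.24 and -7.95. The difference for CUP1-1 (5.56 ± 2.09) lost its call without WT replicate 1 or 2, dbp2 replicate 2, or any of the 4 BMA64-1A libraries, and its value ranged there from 4.83 to 6.12. The xrn1 effect exceeded the MTR4 effect at 5461 features and fell short at 2824 (2213 and 5449 in relative terms), with 6.30, 5.70 and 4.72 for ARG1, PHO5 and ATG41 and -9.14 and -8.98 for CUT433 and CUT342 among features of that density. Between the wild types themselves, 1109 features were higher and 3198 lower in WT-Dox than in WT, at a median of -0.15, so strain background and doxycycline differ along with the mutation in the contrasts with the MTR4 effect.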

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

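Chosen after the result was seen were the tests of the shift of most features, of LYS2 and MET17, of XUTs against genes matched on level, and of genes with opposite directions. The remaining test of XUTs was written before.

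Most features have a higher density per spike-in RNA in the mutants, which less spike-in RNA per yeast RNA could give. In xrn1 the snoRNA median lies 2.02 below the protein-coding one (-2.02, interval -2.10 to -1.91), so a single common factor is excluded as the whole account. In tet-MTR4-Dox the mitochondrial median differs by -0.76 (-0.90 to -0.54), so there too a common factor acting alone cannot give both medians. In dbp2 the mitochondrial difference is -0.11 (-0.24 to 0.12) and the snoRNA one -0.02, so there a common factor may account for the shift. The intervals resample features and not libraries. A common factor of full size, joined to a fall of snoRNAs or mitochondrial RNAs, would give the same differences. None of this separates such a factor, or one of smaller size, from a rise in RNA per cell.

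XUTs rise more than the median protein-coding gene, which weak features of any class might do. Against protein-coding genes matched on level, the XUT excess is -0.28 in dbp2 (-0.46 to -0.12), which that explanation fits. In tet-MTR4-Dox the excess is 0.83 (0.67 to 0.97), against 1.98 over all protein-coding genes. That excludes level as the whole account, but not as a part of it. In xrn1 the excess is 0.10 (-0.06 to 0.28), and the test cannot tell. These intervals resample genes and not libraries. A constant background as large as the whole rise of the XUT median density is excluded in dbp2 and tet-MTR4-Dox. There at least 11.5% and 12.6% of nuclear features lie below 0.5 times that rise. A smaller background, which could give part of the rise, was not tested.

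The dbp2 libraries lack LYS2 reads and hold MET17 reads, unlike the WT of the same background. Reads of the BMA64-1A strains mixed in would need more LEU2, whose highest density is 0.00229 of the need, which excludes them, while a strain with MET17 and without LEU2 was not tested. An exchange of libraries is excluded as DBP2 elsewhere is at 0.988 of WT or more. A background that differs at these loci could be the cause, and 29 of 31 other sulfur and lysine genes are called in relative terms (9 higher and 20 lower), but so are 2217 higher and 2260 lower of 5613 protein-coding genes. No value here separates a background from the deletion, so the test cannot tell.

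Some genes moved in opposite directions in different mutants, and background and doxycycline differ as well in the pairs with tet-MTR4-Dox. Called opposite ways per spike-in RNA in xrn1 and tet-MTR4-Dox were 288 protein-coding genes, 1 XUT and 20 snoRNAs, and in dbp2 and tet-MTR4-Dox 232, 16 and 4. In xrn1 and dbp2, which share WT, they were 404, 16 and 19. In relative terms these were 1051, 95 and 70, then 538, 120 and 18, and for xrn1 and dbp2 881, 80 and 20. The features named from the pairs with tet-MTR4-Dox were picked for that direction, so the limma contrast of their effects (log2) gives the size and is no further test. The effect in xrn1 minus that in tet-MTR4-Dox was -3.97 for YBR032W, -3.26 for HUG1, -2.96 for CUT287, -4.92 for CUT437, -1.59 for IMD2, -2.57 for snR36, -3.74 for snR67, -4.04 for snR128 and -3.03 for snR41. It was 3.54 for SDH1, 6.30 for ARG1, 5.77 for ARG3, 4.38 for ARG4, 5.90 for XUT0788 and 3.51 for MUP1. The effect in dbp2 minus that in tet-MTR4-Dox was -1.67 for IMD2, -2.90 for NUT1082, -4.11 for snR8, -1.85 for ADE12, -1.65 for RPL7B, -4.45 for ADE17, 3.55 for ARG3 and 5.85 for XUT0788. In tet-MTR4-Dox the values of IMD2, NUT1082, ADE12 and RPL7B lay below 0 on all kept features (-0.081, -0.15, -0.35 and -0.23), where ADE12 alone passed limma (adjusted p = 1.2e-05, against 0.143 for IMD2, 0.379 for NUT1082 and 0.0601 for RPL7B). Those of CUT287 and snR36 lay below 0 on snoRNAs (-0.56 and -0.67).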

How the results depend on the processing

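Chosen after the result was seen were the settings with voom, lists against all kept features and genes matched on level. Each group has 2 libraries, replicate numbers share only a label, and scaling on ERCC RNAs sets the direction of most counts. Filters and folds change counts by construction, as fewer features are tested or counted. For the other changed results the cause was not tested. TMM, edgeR, DESeq2, features without overlaps and antisense partners were not run. Correlations are given in the order dbp2 with tet-MTR4-Dox, xrn1 with dbp2, and xrn1 with tet-MTR4-Dox, and other values in the order xrn1, dbp2, tet-MTR4-Dox.

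Only XUTs: correlations 0.0556, 0.308 and -0.247. Only protein-coding genes: 0.613, 0.483 and 0.391. A pseudocount 4 times smaller: NUT minus protein-coding median in xrn1 0.154, correlations 0.443, 0.444 and 0.112. A pseudocount 4 times larger: XUT minus protein-coding in xrn1 0.00506, in dbp2 CUT 0.00169, NUT -0.0929 and snoRNA 0.0236, correlations 0.259, 0.359 and -0.192, XUT camera p in xrn1 0.810.

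No filter: correlation of dbp2 with tet-MTR4-Dox 0.358, XUT camera p in xrn1 0.972. A stricter filter: XUTs higher 892, 817 and 887, NUTs higher 595, 598 and 665, XUTs higher in both dbp2 and tet-MTR4-Dox 810 and in all 3 comparisons 807, NUT minus protein-coding in xrn1 0.0240, correlations 0.418 (dbp2 with tet-MTR4-Dox) and 0.0245 (xrn1 with tet-MTR4-Dox).

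Rescaled on protein-coding genes: in xrn1 4066 features higher and 3188 lower, XUTs 904, CUTs 173, NUTs 525 and snoRNAs 0 higher. In dbp2 4322 higher and 2645 lower, XUTs 817, CUTs 437, NUTs 669 and snoRNAs 20 higher. In tet-MTR4-Dox 2371 lower. For xrn1 against dbp2 3358 higher and 3812 lower, for the xrn1 effect minus the MTR4 effect 2213 and 5449. XUTs higher in both helicase mutants 785 and in all 3 comparisons 584. NUT minus protein-coding in xrn1 0.197, correlations 0.454, 0.471 and 0.163. In xrn1 DBP2 -1.71, MTR4 -1.31 and LYS2 -0.073, RTT103 -0.083, RAI1 -0.154, SKI8 -0.258, HTZ1 -0.640 and HHF2 -0.687, in dbp2 SKI8 -0.270 and CAF40 -0.027, in tet-MTR4-Dox XRN1 -0.26. XUT camera p 5.2e-10 in xrn1 and 7.5e-06 in dbp2. Lists where camera turned, as median minus protein-coding: in xrn1 Gcn4 -0.117, meiosis 0.488, PAU 0.943.

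Rescaled on all kept features: in xrn1 3534 higher and 3675 lower, XUTs 838, CUTs 146, NUTs 479 and snoRNAs 0 higher. In dbp2 3335 higher and 3380 lower, XUTs 701, CUTs 343, NUTs 550 and snoRNAs 14 higher. In tet-MTR4-Dox 4315 higher and 4331 lower. For xrn1 against dbp2 3548 and 3589, for the dbp2 effect minus the MTR4 effect 3835 higher. XUTs higher in both 627 and in all 3 comparisons 459. NUT minus protein-coding in xrn1 0.234, correlations 0.469, 0.480 and 0.180. In xrn1 DBP2 -1.85, MTR4 -1.45, LYS2 -0.21, RTT103 -0.216, RAI1 -0.288, SKI7 -0.053, SKI8 -0.392, UPF3 -0.049, HTZ1 -0.774 and HHF2 -0.822. In dbp2 TRF5 -0.082, SKI8 -0.451, CAF40 -0.207, SAG1 -0.150 and MF(ALPHA)2 -0.0067. In tet-MTR4-Dox XRN1 -0.83, DBP2 -0.19, IMD2 -0.081, NUT1082 -0.15, ADE12 -0.35, RPL7B -0.23, RTT103 -0.064, RAI1 -0.264, SKI7 -0.150, SKI3 -0.399, UPF3 -0.042, NMD2 -0.122, CDC39 -0.269, CDC36 -0.354, IMP3 -0.0088, RPC34 -0.168 and RPC19 -0.175. XUT camera p 6.1e-12 in xrn1 and 3.8e-08 in dbp2. Lists where camera turned, as median minus protein-coding: in xrn1 Gcn4 -0.118, meiosis 0.495, PAU 0.948, and in tet-MTR4-Dox ribosome biogenesis 0.0112.

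Rescaled on snoRNAs, which themselves rose in tet-MTR4-Dox (median log2 2.15), so that values there are lowered by construction: in xrn1 51 lower. In dbp2 4187 higher and 1507 lower, CUTs 505, NUTs 667 and snoRNAs 27 higher. In tet-MTR4-Dox 3227 higher and 5437 lower, XUTs 941 and snoRNAs 33 higher. For xrn1 against dbp2 250 lower, for the dbp2 effect minus the MTR4 effect 6024 and 2218, for the xrn1 effect minus the MTR4 effect 1055 lower. XUTs higher in both 587 and in all 3 comparisons 585. NUT minus protein-coding in xrn1 -0.0415, correlations 0.451 (dbp2 with tet-MTR4-Dox) and 0.0454 (xrn1 with tet-MTR4-Dox). In dbp2 SKI8 -0.154. In tet-MTR4-Dox XRN1 -1.63, DBP2 -0.996, MPP6 -0.56, RRP46 -0.80, IMD2 -0.89, SYF2 -0.23, MUD1 -0.29, CUT287 -0.56, snR36 -0.67, NUT1082 -0.94, ADE12 -1.16, RPL7B -1.04, AIR2 -0.420, EDC1 -0.038, DCS2 -0.346, RTT103 -0.850, RAI1 -1.063, SKI7 -0.933, SKI3 -1.192, UPF3 -0.834, NMD2 -0.916, CDC39 -1.073, CDC36 -1.153, PRP5 -0.704, FAL1 -0.751, GSC2 -0.0099, UTP20 -0.603, RPF1 -0.718, NOP15 -0.773, IMP3 -0.813, QCR9 -0.800, MFA2 -0.641, SAG1 -0.691, RPC34 -0.969, RPC19 -0.982, MSL1 -0.330, SMD3 -0.512, NAB2 -0.316 and THO2 -0.537. XUT camera p 0.00089 in xrn1 and 1.2e-06 in dbp2. Lists where camera turned, as median minus protein-coding: stress in xrn1 0.358, ribosome biogenesis in tet-MTR4-Dox 0.00058.

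At 2-fold or more: in xrn1 12 lower and 3 snoRNAs higher, in dbp2 4534 higher, 77 lower, 691 NUTs and 28 snoRNAs higher, in tet-MTR4-Dox 30 lower, for xrn1 against dbp2 4831 and 330, for the dbp2 effect minus the MTR4 effect 230 higher and for the xrn1 effect minus the MTR4 effect 3324 higher. At an adjusted p under 0.01: 52 lower in xrn1. Camera with an estimated correlation: XUT p in tet-MTR4-Dox 0.0998.

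With voom: NUT minus protein-coding in xrn1 0.259, correlations 0.456, 0.466 and 0.148, XUT camera p 0.0188 in xrn1 and 0.295 in dbp2. Lists against all kept features: the camera direction of ribosome biogenesis in xrn1 turned upward (median minus protein-coding -0.821). Camera calls lost there, with adjusted p: in xrn1 ribosome biogenesis 0.892, phosphate 0.240, meiosis 0.909, haploid 0.495, MATa 0.525 and Nrd1 and Nab3 attenuated 0.527, and in tet-MTR4-Dox ribosome biogenesis 0.511 and splicing 0.372. Gained: in xrn1 splicing 0.0103, in dbp2 exosome 0.0326, MATa 0.0419 and haploid 0.0445, and in tet-MTR4-Dox respiration 0.0038 and iron 0.0445, each lost with an estimated correlation (0.636 to 0.958). Genes matched on level: XUT excess 0.101 in xrn1 and -0.277 in dbp2.

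With a library left out, features lower in xrn1 ranged from 49 (without xrn1 replicate 2) to 105 (without xrn1 replicate 1), the correlation of dbp2 with tet-MTR4-Dox from 0.355 (without WT replicate 1) to 0.392 (without WT replicate 2), and the snoRNA minus protein-coding median in dbp2 from -0.0622 (without WT replicate 1) to 0.0748 (without WT replicate 2). That last value was also above 0 without dbp2 replicate 2 (0.0310), and MTR4 in dbp2 ran from -0.0862 (without WT replicate 2) to 0.00272 (without WT replicate 1). With replicate number as a block, 9192 features were higher and 87 lower in xrn1, 8223 and 524 in dbp2, and 8839 and 319 in tet-MTR4-Dox.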

Other observations

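These observations were chosen after their values were seen. In 22 cases a NUT had the reads of a snoRNA within 5% in each of the 8 libraries other than tet-MTR4-Dox. That rule sets the low shares of those 8 libraries, so part of any contrast with tet-MTR4-Dox is built in. The median share of its reads outside the snoRNA was 0.247% and 0.318% in WT, 0.587% and 0.595% in xrn1, 0.449% and 0.466% in dbp2, 0.290% and 0.273% in WT-Dox, and 10.3% and 11.1% in tet-MTR4-Dox.

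The 40 snoRNAs shorter than 150 nt rose by a median of 3.69 in tet-MTR4-Dox and the 36 longer ones by 1.61 (log2).

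The 4 features of the 2-micron plasmid, R0010W (FLP1), R0020C, R0030W and R0040C, rose by 3.46, 1.62, 0.97 and 3.44 (log2) in xrn1, by 3.71, 0.68, 1.81 and 2.01 in dbp2, and by 2.62, 2.15, 1.55 and 2.14 in tet-MTR4-Dox. In relative terms these were 1.55, -0.29, -0.93 and 1.52 in xrn1, 2.89, -0.14, 0.99 and 1.19 in dbp2, and 1.78, 1.30, 0.70 and 1.29 in tet-MTR4-Dox.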
